A study of Mus musculus with 9 samples.

How the data were processed

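Poly(A) RNA was sequenced from 9 libraries of Gr1-, CD11b- and CD45-positive cells that had been sorted from a mouse prostate cancer model (Pten pc-/-, strain C57BL/6) and divided by C12FDG staining. Per the labels, RNA was extracted with TRIzol and treated with DNase, poly(A) RNA was isolated with magnetic beads, and the libraries were sequenced on an Illumina NextSeq instrument. The library construction kit and its handling of strand are not given in the sources used here. The submitters' processing notes name FastQC, STAR 2.5.2a, DESeq2 and limma, without roles or an order, and the genome builds GRCm38 and mm10. The annotation release and the read counter are not given in the sources used here.

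The authors deposited a table of raw counts for 52550 Ensembl genes, of which 26994 had a count in at least 1 library. They also deposited a second table of log2 values for those 26994 genes. In that table, tested on the values, the mean of the libraries titled old equalled the mean of the other libraries for each gene, with a largest difference of 6e-09, so the deposited log2 values hold no difference between these sets. Differences between C12FDG-positive and C12FDG-negative replicate 1 of the libraries not titled old followed the log2 ratio of the raw counts. The slope was 0.998 over 134 genes with at least 2000 counts, and other pairs of libraries were not checked. The raw counts were used for every main result, and the log2 values only for an alternative. Symbols and coordinates came from the GENCODE M21 annotation of GRCm38, in which 52403 of the 52550 identifiers had a symbol.

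Groups came from the titles. These gave 3 C12FDG-positive and 2 C12FDG-negative libraries with no further mark, and 2 of each with the word old. The labels do not say what old means, so these libraries are called the marked set and the others the unmarked set. The labels do not say whether libraries came from separate mice, so p-values measure only the spread between these libraries, which may be in part technical.

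Gene counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (robust = FALSE), with TMM scaling and filterByExpr on the 4 groups, which left 13301 genes. These genes held 99.67% to 99.93% of the counts of a library. The main comparison fitted C12FDG class and the title mark as additive terms on all 9 libraries. The comparisons within each set and the difference between sets came from a fit of 4 group means on the same libraries. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Standard errors are the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled, and each mean is given with the SD over libraries. Where every library of a group had 0 counts, a fold was computed against 3 counts over the group and is a lower bound that covers counting error only.

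The tests, the named genes and 36 gene lists were chosen before the data were examined. Named genes of the main comparison were up to 12 in each direction with the largest fold change among genes that passed with the same sign in both sets and had a mean log2 CPM of at least 1, leaving out predicted genes. Where fewer than 5 passed, the genes with the smallest p filled up to 5. In the other comparisons 5 in each direction were taken by the same rule. Glb1, Cdkn1a, Cdkn2a, Lmnb1, Apoe, Trem2, Ptprc, Itgam, Ly6g and Ly6c2 were named whatever their p, and each list gave up to 4 members with the smallest p. Lists with at least 5 tested members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, then with an estimated correlation and with fry. The mean log2 CPM of each of the marker lists of other cell types was also compared by a two-sided exact permutation test that rearranged C12FDG labels within each set (60 arrangements, smallest p 0.0167).

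Counts were simulated for the 13301 genes from the means, dispersions and library sizes of these data, with 200 changed genes in each of 3 runs. The changed genes had a mean log2 CPM of at least 1, so the shares called do not cover tested genes below that level. For the main comparison, 5.3% of the genes changed 2-fold were called, 64% of those changed 4-fold, 91.3% at 8-fold and 98.7% at 16-fold, with 19 false calls beside 389 true ones. For the comparison of the sets these shares were 4%, 62%, 87.3% and 98.7%. In those runs the other genes had no difference between the sets, whereas 6639 of the 13301 real genes differed. The shares therefore do not measure recovery where so many genes differ. Of 36 random lists, camera called the 1 list raised 4-fold and no other. The simulated genes were drawn independently, whereas the real lists had estimated correlations of up to 0.791 (ribosomal proteins). This simulation therefore does not measure false calls among lists whose members move together.

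Library totals ran from 6143677 to 25553210 counts, which limits the precision for genes of few counts in the shallow libraries. Libraries of a group differed by more than counting noise, with a chi-square per degree of freedom of 39.6 to 469. Alternatives were other scalings (RLE and upper quartile), other filters on low counts, robust estimation, DESeq2 1.42.0, limma-voom, a model without the mark, a replicate block, each set alone, each library left out, the second table, other thresholds, and other settings of the list tests. DESeq2 was run on all 26994 genes with a count, without filterByExpr, so its counts differ from the main ones in the filter as well as the method. After the data were examined, 3 alternatives were added: genes without exon overlap on the other strand, every library thinned to the smallest total, and removal of the trend with exon length.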

Results

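Sorted Gr1-, CD11b- and CD45-positive myeloid cells, called myeloid-derived suppressor cells by the submitters, were profiled from a mouse prostate cancer model of the genotype Pten pc-/-. Gr1 antibodies bind Ly6G and Ly6C, surface proteins of neutrophils and monocytes. The cells were divided by C12FDG, a substrate that turns fluorescent when cleaved by beta-galactosidase, an enzyme whose lysosomal activity is used as a sign of senescence. The series was designed to compare senescent with non-senescent cells. The unmarked set held 3 C12FDG-positive libraries of 19671655, 18927354 and 6143677 counts and 2 C12FDG-negative libraries of 24018458 and 25553210 counts. The set marked old in the titles held 2 positive libraries of 6773278 and 6532335 counts and 2 negative libraries of 11346773 and 7180605 counts. Between 12480 and 20180 genes were detected in a library. Across genes, the log2 CPM of 2 libraries correlated at 0.83 to 0.98 within a set and at 0.56 to 0.77 between sets, and the first principal component (61.9% of the variance) separated the sets.

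C12FDG-positive cells expressed more of the genes for complement C1q, for the loading of antigen on class II molecules and for several macrophage proteins. The C1q subunit genes C1qa, C1qb and C1qc, which lie side by side on chromosome 4 (GRCm38; 136895917 to 136898803 for C1qa, 136880129 to 136886187 for C1qb and 136889804 to 136893065 for C1qc), rose by 2.66 ± 0.39, 3.26 ± 0.47 and 3.24 ± 0.49 on the log2 scale (SE; 5 against 4 libraries; adjusted p = 0.0345 each, edgeR). In the unmarked set C1qb stood at 53.8 ± 7.54 CPM (SD, n = 3) in positive cells and 9.99 ± 1.71 CPM (n = 2) in negative cells. In the marked set it stood at 504 ± 312 CPM (n = 2) and 24.8 ± 6.04 CPM (n = 2). Mafb, a transcription factor of macrophages (chromosome 2, 160363703 to 160367065), rose by 3.81 ± 0.62 (adjusted p = 0.0345).

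In all, 14 of 13301 genes were higher and 1 was lower in C12FDG-positive cells at an adjusted p of 0.05 (edgeR). This balance depended on the processing. It was 306 higher and 224 lower with DESeq2, which was run without filterByExpr, and 60 and 2 with limma-voom. With edgeR without a filter on low counts it was 238 and 251. Retnla, a secreted protein of alternatively activated macrophages (chromosome 16), rose by 6.75 ± 0.86 (adjusted p = 0.0271). Its size rests on 7 counts in negative replicate 1 of the unmarked set, without which the negative libraries had 0 counts and the fold no finite value, and limma on the second table gave 4.52. Lpl, lipoprotein lipase, rose by 3.13 ± 0.51, Pld4, a lysosomal nuclease, by 2.91 ± 0.46 and Ly86, the partner of the receptor Cd180, by 2.89 ± 0.47 (adjusted p = 0.0345 each). Crip1 rose by 3.18 ± 0.55 (adjusted p = 0.0454). H2-DMb1 and H2-DMa, chains of the class II peptide loader on chromosome 17, rose by 3.56 ± 0.55 and 3.25 ± 0.51, and Tmem176a by 2.68 ± 0.41 (adjusted p = 0.0345 each). H2-DMa and Tmem176a overlap exons of a gene on the other strand, and their counts are uncertain where reads of both strands were counted. The other 2 genes that passed were Cd74, the class II invariant chain (2.33 ± 0.39; adjusted p = 0.0391), and Tagln2 (1.90), which fell outside the naming rule and was named after its value was seen.

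The gene that fell was Muc3, a mucin (chromosome 5), at -2.85 ± 0.49 (adjusted p = 0.0454). The next genes in that direction did not pass: Pomk (-2.73 ± 0.52; adjusted p = 0.0813), Ostm1 (-1.70 ± 0.33; 0.0813), Hgsnat (-1.89 ± 0.37; 0.0902) and Plcxd2 (-1.73 ± 0.36; 0.116). Ostm1 and Hgsnat encode lysosomal membrane proteins, and Ostm1 overlaps exons on the other strand.

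The gene count rested on single libraries. With edgeR it was 0 without C12FDG-positive replicate 2 (1729 genes at an unadjusted p under 0.05) or replicate 3 (1870 genes) of the unmarked set, and 0 without the title mark in the model (659 genes). It was 1 without positive or negative replicate 1 of the unmarked set, 3 without positive replicate 2 of the marked set, 44 without negative replicate 2 of the unmarked set, 32 without negative replicate 2 of the marked set, 530 with DESeq2 and 62 with limma-voom.

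**Figure D1:**
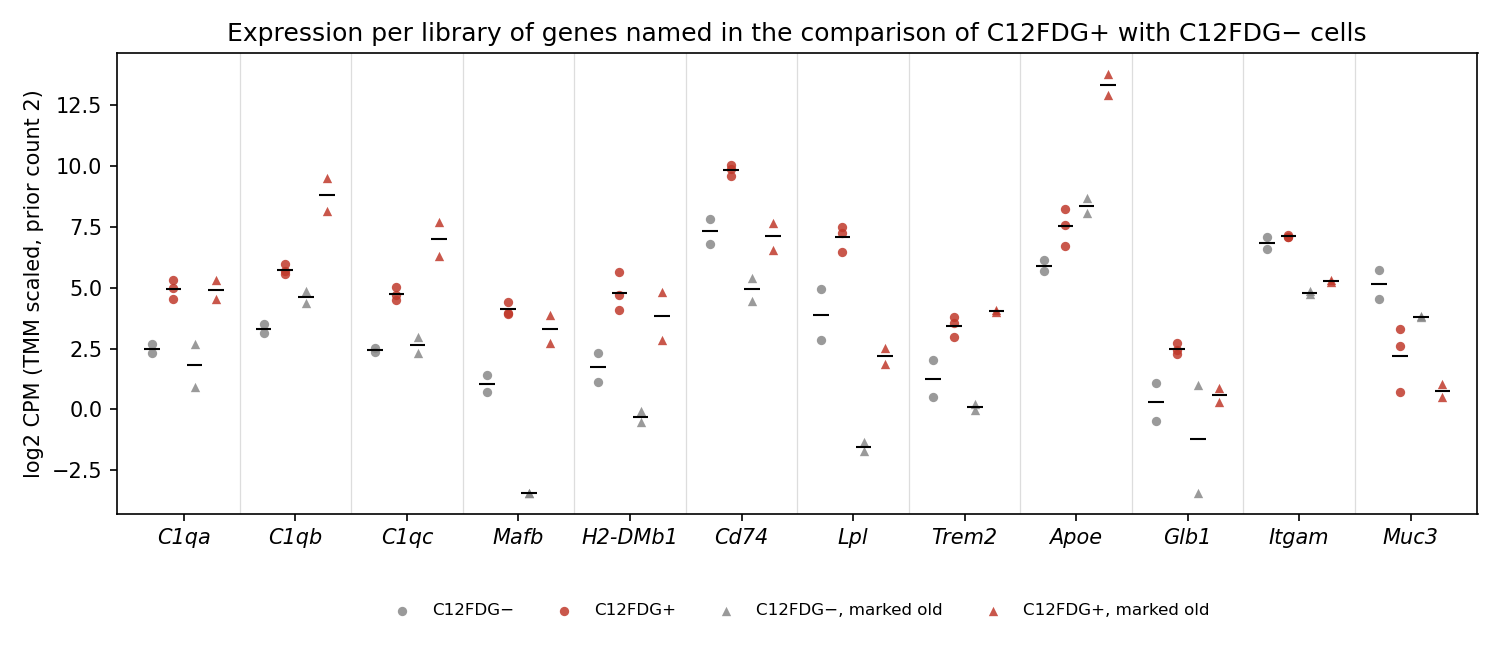
Log2 CPM (vertical axis, TMM scaled, prior count 2) of 12 named genes (horizontal axis) in each of the 9 libraries, with circles for the unmarked set, triangles for the marked set, red for C12FDG-positive and grey for C12FDG-negative cells, and a bar at each group mean. C1qb lies at 5.58 to 9.50 in the positive and 3.15 to 4.86 in the negative libraries, whereas Itgam lies at 7.07 to 7.17 and 6.61 to 7.09 in the unmarked set. The value of -3.42 stands for 0 counts.

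Of 36 gene lists 11 were higher and 3 lower in C12FDG-positive cells, and 11 of 100 splits of the 9 libraries, the real one included, gave at least as many. Some of these splits exchanged only 1 library of the real one or nearly reversed it, so this share is no chance level. Macrophage markers rose as a group. Of 19 tested members, of which only Marco had 0 counts in all negative libraries, 4 rose over all genes tested, 12 rose and 1 fell adjusted over the list alone, and the median log2 fold change was 2.58 (camera adjusted p = 1.97e-09; adjusted p = 0.0151 with an estimated correlation). Besides C1q and Mafb, the platelet factor Pf4 (2.87 ± 0.52; adjusted p = 0.0625 over all genes) and the syndecan Sdc3 (2.24 ± 0.44; 0.0865) passed over the list alone. The widely used markers Cd68 (-0.86 ± 0.52), Adgre1, which encodes F4/80 (-0.43 ± 0.56), and Hmox1 (-1.12 ± 0.43) had negative values, of which Hmox1 passed over the list alone. The mean log2 CPM of the list ran from 4.05 to 4.29 in the positive and from 2.11 to 2.40 in the negative libraries of the unmarked set, and from 2.77 to 3.18 and from 0.90 to 1.42 in the marked set. The difference of 1.85 was higher than in the 59 other arrangements within sets (exact permutation p = 0.0167, the smallest possible; adjusted p = 0.0583 over 14 marker lists). Phagocytosis and complement genes, which share 8 genes with this list, rose with 3 of 25 members over all genes and 10 over the list alone (camera adjusted p = 5.19e-06; adjusted p = 0.0242 with an estimated correlation).

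Genes of class II antigen presentation rose with 3 of 15 members over all genes and 11 adjusted over the list alone, at a median of 1.82 (camera adjusted p = 1.97e-09; adjusted p = 0.0668 with an estimated correlation). H2-Ab1 reached 2.53 ± 0.45 (adjusted p = 0.0532 over all genes) and the class II transactivator Ciita 3.33 ± 0.67 (0.1). The 16 class I genes did not pass as a list (camera adjusted p = 0.199), with none past either threshold.

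Markers of other myeloid cells were higher in the same libraries. Monocyte markers passed with 0 of 22 members over all genes and 1 over the list alone, Fn1 (2.63 ± 0.67), and camera gave an adjusted p of 0.000168 (adjusted p = 0.0584 with an estimated correlation). Dendritic cell markers passed with 0 of 14 members and 7 over the list alone, among them Clec10a (3.05 ± 0.74), Ccl22 and Ccl17 (camera adjusted p = 0.00176; adjusted p = 0.391 with an estimated correlation). Granule genes of neutrophil precursors passed with 0 of 22 members and 7 over the list alone, among them Prtn3 (2.96 ± 0.94), Ngp (1.92 ± 0.63) and Lyz2 (1.43 ± 0.41), with a camera adjusted p of 0.000408 (adjusted p = 0.159 with an estimated correlation). The differences of the list means were 0.99 for monocytes, 1.12 for dendritic cells and 0.81 for neutrophil precursors (exact permutation p = 0.0167 each, adjusted p = 0.0583). Within the unmarked set camera gave adjusted p = 0.000124, 3.5e-05 and 1.72e-05 for the monocyte, dendritic cell and precursor lists, and within the marked set 0.0544, 0.319 and 0.138, where Ccl22 had 0 counts in all 4 libraries and Clec10a and Ccl17 at most 2 in any. The difference between sets did not pass (adjusted p = 0.778, 0.131 and 0.438). Mature neutrophil markers differed by 0.36 (exact permutation p = 0.567; camera adjusted p = 0.0978; none of 32 past either threshold). Within the marked set camera with the preset correlation called them higher (adjusted p = 0.00197). The list means overlapped there, at 9.37 and 8.57 in the positive and 8.86 and 7.32 in the negative libraries. Within the unmarked set the direction was down and the list did not pass (camera adjusted p = 0.587). T cell markers differed by -0.19 (exact permutation p = 0.4; camera adjusted p = 0.823).

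The genes for the sort showed no difference past the threshold. Ptprc (CD45) stood at 0.14 ± 0.32 (adjusted p = 0.887, edgeR), Itgam (CD11b) at 0.34 ± 0.26 (0.588), Ly6g at 0.61 ± 0.46 (0.593) and Ly6c2 at 1.19 ± 0.40 (0.209), and the list of 5 had a camera adjusted p of 0.247 with none past over the list alone.

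**Figure D2:**
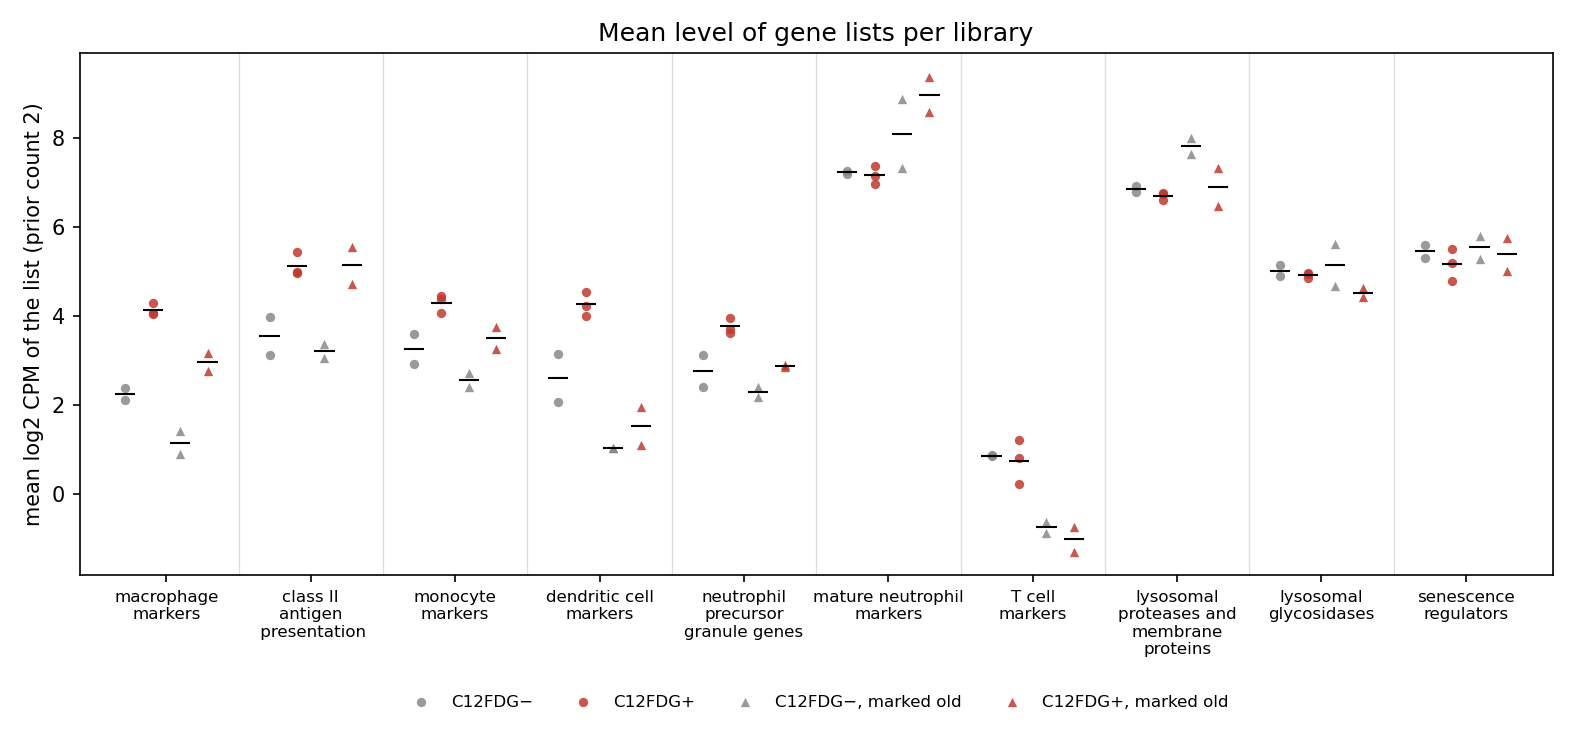
Mean log2 CPM (vertical axis) of 10 gene lists (horizontal axis) in each library, with symbols as in the plot of single genes and bars at group means. The macrophage list lies at 2.77 or above in the positive and at 2.40 or below in the negative libraries, whereas the groups overlap for the senescence regulators.

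Glb1, which encodes the beta-galactosidase behind the staining (chromosome 9, 114401076 to 114474898), was not called. Its log2 fold change was 1.49 ± 0.76 (adjusted p = 0.393, edgeR), from 5.53 ± 0.88 CPM (SD, n = 3) against 1.33 ± 0.99 CPM (n = 2) in the unmarked set. In the marked set it had 4 counts in each positive library and 0 and 9 in the negative ones, so that no difference was detectable at this depth. The 18 lysosomal glycosidases did not pass as a list (camera adjusted p = 0.0978), with 3 lower over the list alone, Naglu (-1.94 ± 0.49), Gba (-0.87 ± 0.27) and Fuca2 (-1.13 ± 0.36). Lysosomal proteases and membrane proteins were lower as a list, with 0 of 31 members past over all genes and 3 higher and 9 lower over the list alone, at a median of -0.63 (camera adjusted p = 0.00429; adjusted p = 0.519 with an estimated correlation). This list passed within the marked set (camera adjusted p = 0.0012; median -0.98) and not within the unmarked set (0.37; median -0.26). The proteases Ctss (1.25 ± 0.31) and Ctsh (1.11 ± 0.28) had positive values and the membrane proteins Mcoln1 (-1.03 ± 0.29) and Npc1 (-1.03 ± 0.30) negative ones.

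Regulators of senescence showed no difference past the threshold over all genes. Cdkn1a, which encodes p21, stood at -0.20 ± 0.57 (adjusted p = 0.911) and Lmnb1, lamin B1, at 0.06 ± 0.38 (0.966). The sign of each of these changed under other settings, and Cdkn1a overlaps exons on the other strand. Cdkn2a, which encodes p16 and Arf, had too few counts to be tested, with 18 counts in negative replicate 2 and 7 and 5 in positive replicates 1 and 2 of the unmarked set and 0 in the other 6 libraries. The list had a camera adjusted p of 0.214, with 1 of 25 members lower over the list alone, Mdm2 (-1.84 ± 0.48). Targets of p53 had an adjusted p of 0.199, again with Mdm2 alone past the threshold of the list. Secretory factors linked to senescence had an adjusted p of 0.576, with 2 of 37 members higher over the list alone, Igf1 (4.22 ± 1.02) and Cxcl16 (1.23 ± 0.30).

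Apoe and Trem2, genes of lipid-associated macrophages, had positive values without passing. Trem2 stood at 2.72 ± 0.50 (adjusted p = 0.0699, edgeR), from 11 ± 3.07 CPM (SD, n = 3) against 2.67 ± 1.90 CPM (n = 2) in the unmarked set and 16.3 ± 0.65 CPM (n = 2) against 0.98 ± 0.12 CPM (n = 2) in the marked set. Apoe stood at 3.10 ± 0.71 (adjusted p = 0.14), from 200 ± 99.7 CPM (n = 3) against 60.3 ± 13.4 CPM (n = 2), and 10900 ± 4510 CPM (n = 2) against 337 ± 99.6 CPM (n = 2) in the marked set. Both were higher over the list alone, with Lpl, Lgals1, Anxa2 and Axl, and Gpnmb was lower (-2.10 ± 0.65). Over all genes Lpl alone of the 24 members passed, and the list as a whole did not (camera adjusted p = 0.484; median -0.13, mean 0.26). The list of genes tied to myeloid-derived suppressor cells did not pass either (camera adjusted p = 0.557). Its member Irf8 alone passed over the list (2.57 ± 0.60). Cd84 (-1.17 ± 0.35), Arg1 (1.93 ± 0.62) and Nos2 (-1.89 ± 0.63) did not.

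Genes of the respiratory chain and of the ribosome were higher as lists. Camera gave adjusted p = 6.36e-06 for 35 nuclear subunits of the chain (0 past over all genes or the list alone), 0.000148 for 7 mitochondrial ones (4 over the list alone) and 0.000148 for 41 ribosomal proteins (1 over the list alone, Rps4x). With an estimated correlation the adjusted p values were 0.519, 0.485 and 0.677. Within the unmarked set each of these lists passed (camera adjusted p = 0.00486, 2.63e-10 and 0.000156). Within the marked set the nuclear list passed (0.000133), whereas the mitochondrial (0.696) and ribosomal lists (0.0653) did not. Of the 41 ribosomal proteins, 39 had positive values in the unmarked set and 13 in the marked set. Mitochondrial genes took 0.822% to 1.21% of the counts in the positive and 0.307% to 0.343% in the negative libraries of the unmarked set, and 1.48% to 1.91% and 1.01% to 2.09% in the marked set. Immediate early and dissociation stress genes (0 of 29 over all genes; 1 lower over the list alone, Hspa1a at -1.95 ± 0.44) and hypoxia and glycolysis genes (0 of 30 by either count) were lower as lists, with camera adjusted p of 0.000248 and 0.000168, and adjusted p = 0.519 each with an estimated correlation. The stress genes passed within the unmarked set (camera adjusted p = 3.44e-06) and not within the marked set (0.296). The hypoxia genes passed within both (0.0107 and 0.00244). G2 and M phase genes (0 of 28 by either count) and prostate epithelial markers (0 of 23; Cdh1 and Cldn4 over the list alone) were higher as lists, with adjusted p of 0.0113 and 0.0169, and adjusted p = 0.519 each with an estimated correlation. These 2 lists passed within the unmarked set (camera adjusted p = 2.61e-07 and 3.99e-07). Within the marked set their direction was down and they did not pass (0.696 and 0.658).

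Within the unmarked set (3 against 2), edgeR called 0 genes, with 1084 at an unadjusted p under 0.05 in the fit of all 9 libraries and 0 genes with 2051 of 13819 in a fit of that set alone, while DESeq2 called 166 and limma-voom 0. Without negative replicate 1 or 2 of the marked set edgeR called 1. The smallest p values there belonged to mt-Nd6 (2.93 ± 0.42; adjusted p = 0.209), Clu, Retnla, Mafb and Ccr2 with positive values, and to Muc3, Pomk, Hsph1, Lrrc14b and Plcxd2 with negative ones. Among these, mt-Nd6 and Lrrc14b overlap exons on the other strand. Within the marked set (2 against 2), C1qc (4.53 ± 0.57) and C1qb (4.35 ± 0.56) rose (adjusted p = 0.0373 each, edgeR). Neither was called with a filter of at least 1 CPM in 5 libraries or in a fit of that set alone (0 genes called by edgeR in each, with 1545 and 663 at an unadjusted p under 0.05). Mafb and Retnla had 0 counts in both negative libraries of that set and were at least 30.4-fold and 65.8-fold higher in the positive ones, against a floor of 3 counts over the group. Apoe (5.01 ± 0.75; adjusted p = 0.0653), Pld4, Heg1, Zdhhc20, Psmd1, Dnmt1 and Als2 did not pass, and Heg1, Psmd1 and Als2 overlap exons on the other strand. Without negative replicate 1 of the marked set this count was 1307, and without positive replicate 1, 2 or 3 of the unmarked set, negative replicate 2 or positive replicate 2 of the marked set it was 0, with 958 to 1837 genes at an unadjusted p under 0.05. The count was 6 without negative replicate 1 and 5 without negative replicate 2 of the unmarked set, and 4 without positive replicate 1 of the marked set.

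No gene passed for a difference of the C12FDG effect between the sets (edgeR, smallest adjusted p = 0.825; 768 genes at an unadjusted p under 0.05; DESeq2 11, limma-voom 0). The smallest p values belonged to mt-Nd6, Slc26a10, Psmd1, Mtmr4 and Anxa4 in one direction and Rnf125, Sirpb1b, Rasgrp2, Gpr132 and Atrn in the other. Of these, mt-Nd6, Slc26a10, Psmd1, Anxa4, Sirpb1b and Rasgrp2 overlap exons on the other strand, so their counts are uncertain where reads of both strands were counted. Without negative replicate 1 of the marked set 274 genes passed. Across genes, which are not independent replicates, the differences in the 2 sets correlated at 0.24 and 60.2% had the same sign. Another of the 60 arrangements of the labels gave as high a correlation, and the highest other share was 60.1%.

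The sets themselves differed in 6639 of 13301 genes, 3038 higher and 3601 lower in the marked libraries (edgeR), with a median log2 fold change of -0.44. The split depended on the scaling, with 3565 higher and 2829 lower under RLE (median -0.09) and 3463 and 2891 under upper quartile scaling (median -0.15). With DESeq2, run without filterByExpr, it was 4902 and 3041 of 17387 genes with an adjusted p. The DESeq2 median of 1.36 was taken over all 26994 genes with a count and is not comparable with the other medians. In the marked libraries the 10 most abundant genes took 31.5% to 38% of the counts against 8.55% to 11.7% in the others, and the ferritin gene Fth1 8.17% to 11.2% against 1.84% to 2.36%. Ribosomal RNA with Gm42418 took 2.16% to 11.8% against 0.036% to 0.313%, and haemoglobin genes 0.131% to 0.345% against at most 0.008%. Across genes, log2 CPM correlated with exon length at -0.06 to 0.08 (Spearman) in the marked and 0.29 to 0.33 in the unmarked libraries, and genes are not independent replicates. Within each set the ranges of these 4 shares overlapped between C12FDG-positive and negative libraries.

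Cytosolic ribosomal proteins (31 of 41 higher over all genes, 34 over the list alone) and nuclear subunits of the respiratory chain (28 of 35 higher and 1 lower by either count) rose in the marked libraries, with a camera adjusted p of 3.16e-08 each (adjusted p = 0.802 and 0.768 with an estimated correlation). NF-kB targets (18 of 26 higher and 6 lower; adjusted p = 0.00111) and mature neutrophil markers (18 of 32 higher and 5 lower; 0.00316) were higher as lists too, with the same counts over the list alone and adjusted p = 0.768 and 0.802 with an estimated correlation. By the naming rule the genes higher in the marked set included CT010467.1 (15.89 ± 1.28), Fam57b (12.10 ± 0.68) and Pate2 (9.62 ± 1.12), which overlap exons on the other strand. The size for Pate2 rests on 1 count in positive replicate 2 of the unmarked set. The other genes higher were mt-Ty and H2-Q1, which had 0 counts in the unmarked set and were at least 1680-fold and 362-fold higher. The genes lower by that rule had 0 counts in the marked set. Ccl22, a chemokine, was at least 218-fold lower, Asgr2 102-fold, Nacc1 60.7-fold, n-R5-8s1 45.9-fold and Ptx3 43.7-fold.

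**Figure D3:**
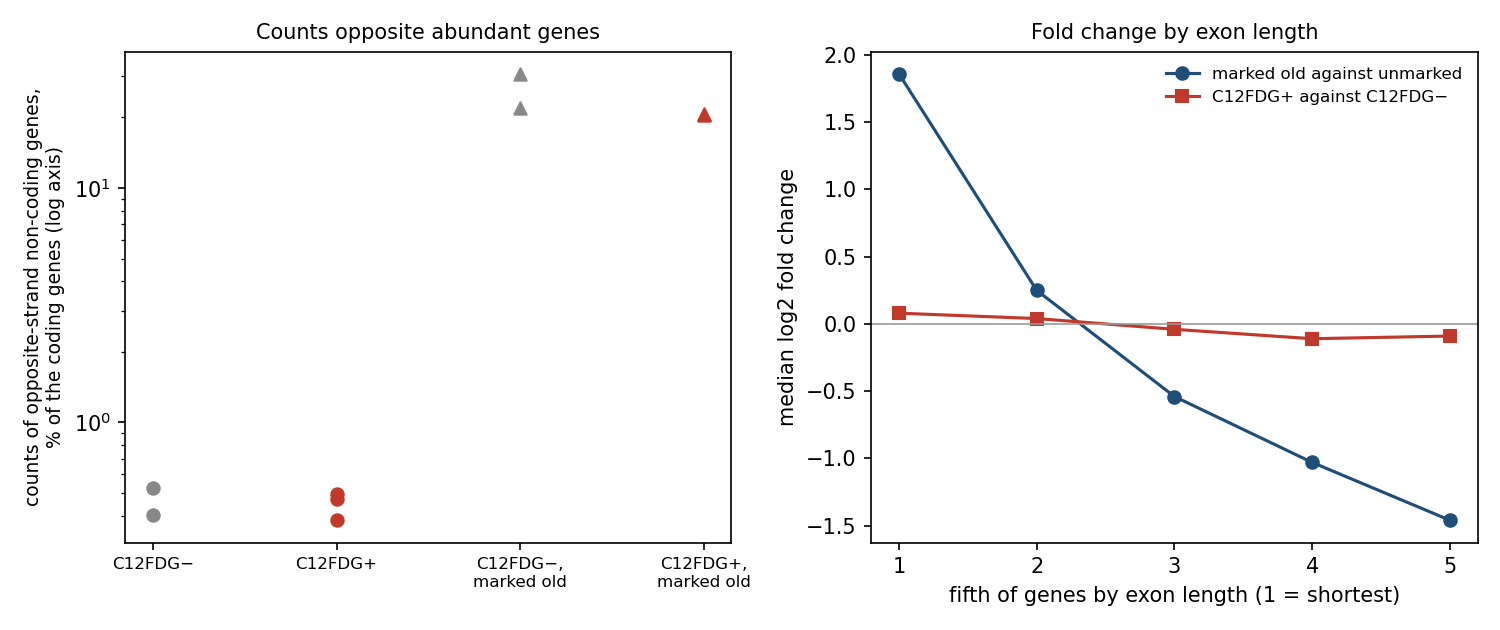
Left, counts of 176 non-coding genes as a percentage of those of the abundant coding gene on the other strand (log axis) in each library by group. Right, the median log2 fold change (vertical axis) of 5 equal groups of genes by exon length (horizontal axis) for the marked against the unmarked libraries (blue) and for C12FDG-positive against negative libraries (red). The percentage lies at 20.5% to 30.7% in the marked and 0.382% to 0.525% in the unmarked libraries, and the blue medians run from 1.86 in the shortest to -1.46 in the longest genes.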

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

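The tests of explanations in this part were chosen after the differences had been seen, except the comparison of medians among well-counted members, which was restricted afterwards to the lists where it could come out either way. The difference between C12FDG-positive and negative cells itself differed between the unmarked and the marked set for 6 of 36 gene lists, by camera on the difference of the 2 effects. The adjusted p was 5.4e-05 for mitochondrial subunits of the respiratory chain, whose mean difference was 1.97 in the unmarked and 0.15 in the marked set. It was 0.000143 for G2 and M phase genes (1.32 and -0.27) and 0.000143 for prostate epithelial markers (1.42 and -0.28). It was 0.000829 for mature neutrophil markers (-0.07 and 0.87), 0.0194 for lysosomal proteases and membrane proteins (-0.15 and -0.92) and 0.0457 for S phase genes (0.76 and -0.38). No single gene passed this test with edgeR.

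A candidate explanation is that members of a list move together and that the preset correlation treats them as nearly independent, since with an estimated correlation the lowest adjusted p of the 6 lists was 0.512. Low counts in the marked libraries are argued against for 3 lists, in which 31 of 31 (lysosomal), 7 of 7 (mitochondrial) and 30 of 32 members (neutrophil) had a mean of at least 20 counts there. In 1 of the 3 others, the epithelial list, the median difference between sets was 2.07 over 7 such members against 1.94 over 23. It was 0.46 over 7 members against 0.99 over 24 in the S phase list and -0.58 over 3 against 1.45 over 28 in the G2 and M phase list, so low counts stay open for these 3 lists together. What old means was not tested, and a biological difference between the sets stays open.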

How the results depend on the processing

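Genes without exon overlap, thinned libraries and removal of the length trend were chosen after the data were examined, and all other alternatives before. The macrophage list passed in 20 of 20 settings (difference of the list mean 1.63 to 2.07), as did phagocytosis and complement (0.96 to 1.20), and class II in 19 (1.33 to 1.95). The list of lysosomal proteases and membrane proteins passed in 17 of 20 (-0.63 to -0.28). C1qb passed in 17 of 22 settings (2.82 to 3.76) and Glb1 in 0 of 22 (1.02 to 2.28). Apart from left-out libraries, values of single genes kept their direction and side of the threshold in 2090 comparisons, lost the call in 36, gained one in 175 and reversed in 8. For lists these numbers were 350, 26, 5 and 7.

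Genes called for C12FDG numbered 489 without a filter on low counts, 530 with DESeq2 (also run without filterByExpr), 62 with limma-voom, 0 without the title mark, 52 with limma on the second table without the mark and 29 at an adjusted p of 0.1, against 15. In the marked set they numbered 350 without a filter, 0 with at least 1 CPM in 5 libraries, 5 after thinning, 327 with DESeq2 and 0 in a fit of that set alone, against 2. In the unmarked set they numbered 179 without a filter and 166 with DESeq2, and for the difference between sets 46 and 11, against 0 each. Between the sets 4156 genes passed without exon overlap on the other strand, where fewer genes (8954) were tested. With an estimated correlation 2 lists passed, and 5 with fry, against 14. The cause was not tested for the others.

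The replicate numbers were not shown to pair the libraries, and the labels do not say what they share. The deviations of same-numbered libraries correlated at -0.15 and -0.23 in the unmarked set and at 0.12 in the marked set, where both pairs must give the same value. With the replicate block 6 genes passed for C12FDG and 0 in the marked set. Under the block Cdkn1a stood at 0.27, Txk at -0.15 and the interferon list at 0.02, each reversed.

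Leaving out 1 library at a time gave 0 to 44 genes for C12FDG, 0 to 1 in the unmarked set, 0 to 1307 in the marked set, 0 to 274 for the difference between sets, 5741 to 7376 between the sets, 14 to 17 lists and 0 to 5 marker lists with an unadjusted exact permutation p under 0.05 (4 with all libraries, each with an adjusted p of 0.0583). The 0 for marker lists came without any 1 C12FDG-positive replicate of the unmarked set. The smallest possible p was 0.0556 there, so no list could pass. Where a group keeps 1 library, it is assumed to vary like the other groups. Values whose sign changed ran from -0.57 to 0.27 for Cdkn1a, -0.06 to 0.36 for Ptprc, -0.19 to 0.20 for Lmnb1, -1.59 to 0.05 for Kit, -0.07 to 1.81 for Txk, -0.18 to 0.44 for the NK cell list, -0.30 to 0.20 for the interferon list and -0.44 to 0.04 for the endothelial list.

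Among other reversals, Cdkn1a stood at 0.04 with limma-voom, 0.13 on the second table and 0.12 there without the mark, Txk at -0.07 (against 0.81) and Kit at 0.47 (against -0.60) with limma-voom, and mt-Nd6 at -0.17 without the title mark. The interferon list stood at 0.02 under upper quartile scaling and 0.05 with at least 1 CPM in 5 libraries, the fibroblast list at -0.11 with that filter and -0.07 without exon overlap, the NK cell list at -0.11 without a filter and the endothelial list at 0.06 with a prior count of 0.5. The cause was not tested.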

Other observations

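The tests of explanations in this part were chosen after the data were examined and, except the removal of the length trend, after the result they measure had been seen. The test of length in each library replaced a first one whose outcome had been seen and did not set the mark apart from other splits of the libraries. Lists not yet described did not pass between C12FDG-positive and negative cells. The camera adjusted p was 0.0625 for erythroid and platelet markers (3 of 9 members higher over the list alone, Pf4, Ppbp and Car2), 0.232 for B and plasma cells (0 of 13), 0.294 for NK cells (0 of 7), 0.294 for eosinophils (1 of 8, Prg2) and 0.329 for mast cells and basophils (0 of 5). It was 0.522 for fibroblasts (0 of 10), 0.484 for endothelial cells (1 of 5 higher, Kdr, and 2 lower, Vwf and Pecam1), 0.524 for S phase (0 of 24), 0.585 for the type I interferon response (0 of 33), 0.37 for NF-kB targets (0 of 26), 0.37 for the unfolded protein response (1 of 22, Sdf2l1) and 0.358 for cholesterol synthesis and uptake (1 of 19, Ldlr). The median and the test had opposite signs for T cells (median 0.10, test down), and the median and the mean for endothelial cells (-0.85 and 0.17). Between the sets, lists also passed for secretory factors linked to senescence (higher in the marked set, adjusted p = 0.00255), class I antigen presentation (higher, 0.00367), erythroid and platelet markers (higher, 0.0224), mitochondrial subunits of the respiratory chain (higher, 0.00152), G2 and M phase (lower, 0.00441) and cholesterol synthesis (lower, 0.0439), none of them with an estimated correlation (lowest adjusted p = 0.768).

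Macrophage and class II genes were higher in C12FDG-positive cells, sorted through a gate that required Gr1, CD11b and CD45. A chance split of the libraries as the source of the 15 called genes is argued against, but not excluded, by other splits. Of 100 splits of the 9 libraries 2 gave as many, the real one and a split of 118 genes that put the 4 marked libraries with positive replicate 3 of the unmarked set. With the mark in the model, that split compares this library with the other 4 of its set and points to a library that stands apart, without which edgeR called 0 genes for C12FDG (1870 at an unadjusted p under 0.05). Of the 60 arrangements within sets only the real one gave as many (highest other 1). For the number of lists the splits cannot decide on chance, although 11 of 100 gave 14 or more (highest other 18). The split with 18 put the 4 negative libraries with positive replicate 1 of the marked set, which is nearly the real split reversed. Splits with 16 lists exchanged only 1 library of the real one. Such splits hold part of the same difference and give no chance level. A lower share of neutrophils that raised every other cell type alike is argued against for the lists compared. The macrophage list rose by 2.04 more than the T cell list and 1.65 more than the fibroblast list (exact permutation p = 0.0167 each). It rose by 1.44 more than the NK and 1.34 more than the B and plasma cell list (0.0333 each). The adjusted p was 0.0333 for each over 6 such contrasts. The T cell (mean log2 CPM -1.28 to 1.22), NK (-2.51 to 0.44) and B and plasma cell lists (-1.54 to 0.35) lay near the floor. A rise could be hidden there, so these contrasts are weak evidence. The fibroblast list lay at 1.12 to 2.33. The monocyte, dendritic cell and precursor lists, which also rose, were not contrasted. Depth is argued against by the 14 of the 15 genes that still passed after thinning. More macrophages among the positive cells and higher expression within the same cells cannot be told apart in bulk RNA: 14 of 19 markers had positive values, but the most abundant, Cd68, stood at -0.86 ± 0.52 (121 to 189 CPM in positive and 190 to 330 CPM in negative libraries of the unmarked set, 680 to 2870 CPM and 1210 to 6300 CPM in the marked set).

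The 6639 genes that differed between the sets exceed every other of 100 splits (1 with as many, highest other 2293), which argues against a chance split. Non-coding genes opposite abundant coding genes are consistent with reads of both strands being counted in the marked libraries, since the lowest ratio to the coding gene there was 39 times the highest in the unmarked libraries. This is not the whole cause, because 4156 genes passed among those without exon overlap on the other strand. A shift to short transcripts may be another part, since log2 CPM correlated with exon length across genes at -0.06 to 0.08 in the marked and 0.29 to 0.33 in the unmarked libraries (gap -0.21), but 5252 genes still passed once the length trend was removed. The age of the mice cannot be told apart from a batch, since 0 libraries have a label that gives an age.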
